A study of Mus musculus with 32 samples.

How the data were processed

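The series measured gene expression in mouse striatum. YAC128 mice carry a human huntingtin transgene with an expanded polyglutamine repeat on a yeast artificial chromosome and serve as a model of Huntington disease. AON12.1 is the antisense oligonucleotide under study, and the series title names the caspase-6 cleavage site of HTT as its target. Per the labels, YAC128 mice received AON12.1, a scrambled oligonucleotide or artificial cerebrospinal fluid (aCSF) into the lateral ventricle, and wild-type (WT) littermates received aCSF. The labels give 3 injections, the first at about 6 months of age and the others 2 and 4 weeks later, of 500 µg oligonucleotide in 10 µL, with tissue taken at 12 months. Each library comes from a separately numbered animal, so the spread between libraries includes the spread between animals. The 4 groups hold 8 libraries each, 32 in all.

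Per the labels' protocols, 100 ng of total RNA per sample was reverse transcribed with a barcoded oligo-dT primer that carries a unique molecular identifier, by a modified mcSCRB-seq method. Such libraries sample the 3' part of polyadenylated transcripts, so a gene's value does not tell which exons its transcripts hold. Per the submitters' processing notes, the tools named are FastQC, cutadapt 2.10, STAR 2.7.5a and HTSeq 0.12.4, with the GRCm39 build. Whether reads were collapsed by molecular identifier, and whether strand was used in counting, is not given in the sources used here. Intervals from the count model rest on the spread between mice and so cover more than counting error.

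The deposited files hold whole-number counts per gene, 1 file per library, not normalized by the authors. Each file has 55420 lines, of which 55415 are features and 5 are summary lines for reads outside any feature, ambiguous, of low quality, unaligned or aligned more than once. The summary lines stayed out of library sizes and tests. Counts outside any feature made up a share of each file's sum, summary lines included, that ranged from 16.3% to 33.7% between libraries, with a mean of 22.8% ± 5.15 (SD, n = 32). Ambiguous counts made up 1.59% on average and counts aligned more than once 8.80%. Gene names came from a GRCm38 annotation matched by Ensembl identifier, and 52081 features with 99.806% of the counts had a name. Since the deposited counts use another build, no coordinates are given, and the GRCm38 annotation served only for names, chromosomes and neighbours. One feature, NM_001388492, has no Ensembl mouse identifier and is reported under its identifier as deposited. Total gene counts per library ran from 658934 to 1419313, with a mean of 958910.

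Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10679 genes. All 32 libraries entered a single TMM-normalized quasi-likelihood fit with 1 coefficient per group, and each comparison was a contrast of that fit. The common biological coefficient of variation was 0.167. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± SE from that fit, and group levels are TMM-normalized CPM ± SD with n = 8. The 6 comparisons were YAC128 aCSF against WT aCSF (genotype), AON12.1 against scrambled, AON12.1 against aCSF, scrambled against aCSF, and each oligonucleotide group against WT. Comparisons that share a group are not independent of each other.

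The gene lists were 45 sets of cell type markers, pathways and dissection markers fixed before the data were examined, together with the comparisons, the tests, a set of other settings and the rule for named genes. Of these, 37 had at least 5 tested members and were tested with camera from limma 3.58.1, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. The same test with a correlation estimated from each list was fixed in advance as a second setting and is given beside each list result. Within each list, calls are given over all genes and adjusted over the list alone. The rule for named genes took Htt, up to 10 called genes in each direction by smallest p in the 4 main comparisons without predicted or sex-linked genes, up to 4 members of each called list by smallest p, and 11 striatal, glial and dissection references. 1110038B12Rik is a Rik name outside this rule and was chosen after its values were seen. Some genes that the rule takes are not reported here.

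To ask whether treatment moved genes toward their WT level, the 200 genes with the smallest genotype p were taken with their sign, and the median signed log2 fold change under treatment was computed, so that a negative value points toward WT. For AON12.1 against scrambled, which shares no library with the genotype comparison, fry from limma gave a p-value, adjusted over 7 settings of this measure. For lists whose members moved both ways, fry's test for change in either direction was adjusted over the 37 lists. Both adjustments were chosen after the p-values were seen. For comparisons with the YAC128 aCSF group, its libraries were split into sets of 4, with 1 set used to choose genes and the other as control, over all 70 ordered splits. Library measures such as the no-feature share and mean log2 CPM of marker lists were compared between groups with exact permutation tests, two-sided, adjusted over a family of 48.

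The gene fits, the list test and the measure of movement toward WT were tested on simulated data made from the real means and library sizes. The other steps were not tested in this way. In a simulated AON12.1 against scrambled comparison of 10545 genes, with 200 changed, edgeR recovered 93% of the genes changed by 2-fold and 69% of those changed by 1.5-fold, and 14 of its 176 calls were false. A comparison simulated without change gave 0 calls in edgeR. Replicate pairs differed by more than sampling noise, with chi-square per degree of freedom from 1.74 to 6.19, so no pair was treated as a single library. All 32 libraries had at most 3 Xist counts and at least 22 Ddx3y counts, the pattern of male mice. The sex gene score used as a covariate, Y-linked genes minus Xist, thus does not contrast the sexes here. The labels give no batch. The animal numbers in the titles start with 18 or 19, and this series served as a covariate and as a split.

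The other settings fixed in advance were another size factor method, leaving out mitochondrial genes, no filter and a stricter filter with a minimum count of 50, DESeq2 1.42.0, limma voom with quality weights, only the 2 groups compared, covariates for number series, sex genes and dissection markers, each number series alone, and each library left out in turn. Settings chosen after seeing the data were the no-feature share as a covariate, alone or with tissue scores, only libraries with a share up to 25%, gene lists without 5 single libraries, the measure of movement toward WT over called genes without 2 of these, and gene lists without C4b.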

Results

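RNA from the striatum of 32 mice was profiled by 3'-end sequencing, with 8 libraries in each of 4 groups. WT and YAC128 mice given aCSF show the effect of the transgene. YAC128 mice given AON12.1, an antisense oligonucleotide directed at the HTT caspase-6 site according to the series title, were compared with YAC128 mice given a scrambled oligonucleotide or aCSF. Total gene counts averaged 893248 ± 170533 in WT aCSF, 1005390 ± 198567 in YAC128 aCSF, 957545 ± 136214 in YAC128 AON12.1 and 979455 ± 204087 in YAC128 scrambled libraries (SD, n = 8 each). At this depth the median SE of a log2 fold change lay near 0.16 in each comparison.

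Mouse Htt (ENSMUSG00000029104, chromosome 5 of GRCm38), the endogenous huntingtin gene, was measured at 89.6 ± 17.4 CPM in WT aCSF and 105 ± 17.5 CPM in YAC128 aCSF mice (SD, n = 8 each). Its level was 102 ± 15.4 CPM with AON12.1 and 101 ± 15.7 CPM with the scrambled oligonucleotide. The log2 fold change was 0.23 ± 0.12 for genotype (adjusted p = 0.422) and 0.02 ± 0.12 for AON12.1 against scrambled (adjusted p = 0.983), and neither passed the test. With the share of counts in no feature as a covariate the genotype value was 0.11 (adjusted p = 0.882). WT replicate 1 stood at 129.5 CPM, against at most 94.4 CPM in the other WT libraries. The 95% interval of the AON12.1 to scrambled ratio ran from 0.865 to 1.19, and that of AON12.1 to aCSF from 0.826 to 1.13. Counts from the human transgene that align to mouse Htt cannot be separated from those of the endogenous gene, so this level is uncertain. Gene-level 3' counts also give no value for the exon or protein site that the oligonucleotide was aimed at. The files contain 1 feature without a mouse Ensembl identifier, NM_001388492, which had 3.40 ± 2.35 CPM in WT and 144 ± 23.9 CPM in YAC128 aCSF mice (SD, n = 8 each). It rose by 5.26 ± 0.23 on the log2 scale with genotype (38.4-fold, adjusted p = 2.58e-20). With AON12.1 it differed by a log2 fold change of 0.11 from the scrambled group (adjusted p = 0.927) and of -0.00 from aCSF (adjusted p = 0.999).

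**Figure D1:**
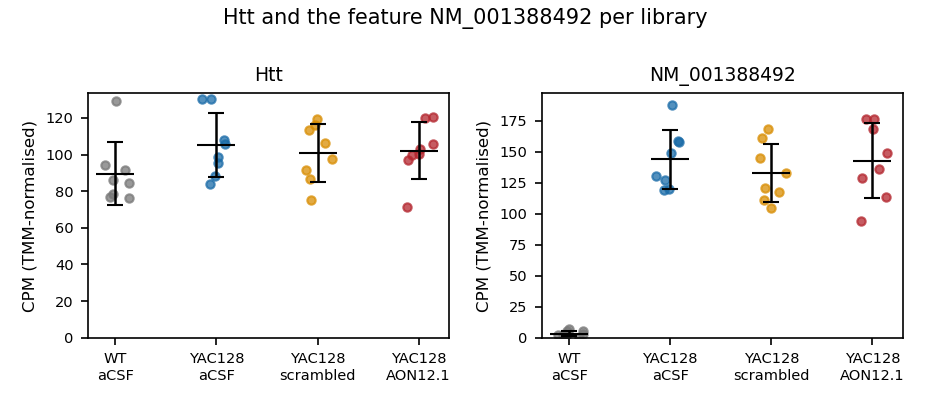
Level in CPM (y axis) of mouse Htt and of the feature NM_001388492 in each library, by group (x axis), with the bar at the group mean ± SD, n = 8. NM_001388492 lies at 6.90 CPM or lower in WT libraries and at 91.4 CPM or higher in YAC128 libraries, while mouse Htt overlaps between all groups.

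The libraries differed in the share of counts that fell in no feature, and this share ran along the main axis of variation. It averaged 19.5% ± 4.40 in WT aCSF, 25.7% ± 4.92 in YAC128 aCSF, 23.8% ± 6.70 in AON12.1 and 22.1% ± 2.41 in scrambled libraries (SD, n = 8 each). The YAC128 aCSF group exceeded WT by 6.12 percentage points (exact permutation test, two-sided, p = 0.0292, adjusted p = 0.319 over 48 tests). Within the animals numbered from 18 the difference was 7.06 points (4 against 3 libraries, exact p = 0.143), and within those numbered from 19 it was 4.20 points (4 against 5, exact p = 0.0952). The first principal component of the 1000 most variable genes held 27.2% of the variance and followed the share with r = 0.962 and rho = 0.960 over 32 libraries. The permutation p was 1e-05 for both, the smallest that 100000 resamples can give. Without the 2 libraries farthest from the median share, r was 0.970. Within the series, r was 0.983 and rho 1.0 over the 11 libraries numbered from 18, and r was 0.949 and rho 0.923 over the 21 numbered from 19 (permutation p = 2e-05 each, the smallest they can give).

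**Figure D2:**
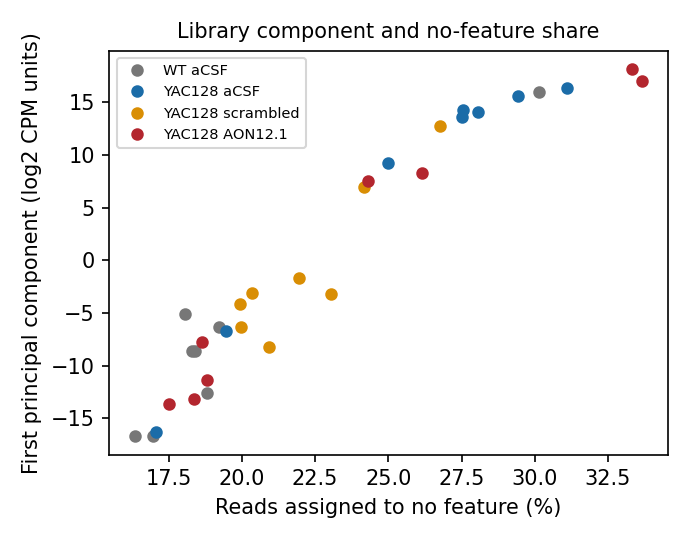
First principal component of log2 CPM over 1000 genes (y axis, in the component's units) against the share of counts in no feature in percent (x axis), 1 point per library and coloured by group. The libraries of all groups follow a single trend, with r = 0.962 over 32 libraries.

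Between YAC128 and WT mice given aCSF, Penk and Adora2a, both expressed in indirect-pathway projection neurons, were lower, and Enpp6 and Spata5 were higher. Penk (ENSMUSG00000045573, chromosome 4), which encodes the enkephalin precursor of indirect-pathway neurons, fell from 4201 ± 1102 to 2488 ± 586 CPM (SD, n = 8 each), a log2 fold change of -0.76 ± 0.16 (adjusted p = 0.0495). Adora2a (ENSMUSG00000020178, chromosome 10), an adenosine receptor of the same neurons, fell from 87.7 ± 19.6 to 49.2 ± 11.9 CPM (-0.83 ± 0.18, adjusted p = 0.0495). Enpp6 (ENSMUSG00000038173, chromosome 8), a choline phosphodiesterase of oligodendrocytes, rose from 16.6 ± 6.30 to 34.7 ± 6.88 CPM (1.08 ± 0.19, adjusted p = 0.00632). Spata5 (ENSMUSG00000027722, chromosome 3), an AAA-family ATPase, rose from 5.39 ± 1.86 to 15.4 ± 3.77 CPM (1.43 ± 0.25, adjusted p = 0.00632).

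The other named genes called for genotype were Anxa5, a calcium-dependent phospholipid-binding protein, higher at 60.7 ± 7.88 against 41.7 ± 6.48 CPM (0.54 ± 0.11, adjusted p = 0.0358), and a further pair that was lower. Il33, an alarmin cytokine, fell from 61.1 ± 11.2 to 36.1 ± 9.48 CPM (-0.78 ± 0.16, adjusted p = 0.0358). Sgk1, a glucocorticoid-induced kinase, fell from 80.2 ± 23.3 to 48.3 ± 15.99 CPM (-0.75 ± 0.16, adjusted p = 0.0398). In all, 8 of 10679 genes were called, 4 higher and 4 lower, and 1340 had an unadjusted p under 0.05 where 534 are due by chance. With the no-feature share as a covariate, 741 genes had an unadjusted p under 0.05. Among libraries with a share up to 25%, which left 3 YAC128 aCSF and 7 WT libraries, 611 did. Much of the excess thus cannot be told apart from the difference in that share. DESeq2 called 54 genes, 3 of them higher, but gave 7 of the 8 genes no adjusted p, and voom called 20. Without WT replicate 1, whose no-feature share was 30.2% against at most 19.2% in the other WT libraries, 142 genes were called, 114 of them higher. The 8 genes had the same sign within both number series, whose libraries also gave the calls, so this is no independent test. With the no-feature share as a covariate, Adora2a (-0.75, adjusted p = 0.270), Penk (-0.66, adjusted p = 0.296), Sgk1 (-0.64, adjusted p = 0.270), Anxa5 (0.54, adjusted p = 0.105) and Il33 (-0.77, adjusted p = 0.105) were no longer called, and the last pair had 0.54 and -0.78 without it. Leaving out 1 library at a time, Spata5 and Enpp6 stayed called in 16 of 16 fits, Il33 in 8, Anxa5 and Sgk1 in 6, Adora2a in 5 and Penk in 4. Spata5 and Enpp6 were not called in either number series alone or among libraries with a no-feature share up to 25%, where fewer libraries enter. In series 18 and 19 Spata5 had 1.67 and 1.46 (adjusted p = 0.388 and 0.264), and Enpp6 1.02 and 1.05 (adjusted p = 0.388 and 0.530). Penk was also not called with the cortex and choroid plexus scores (adjusted p = 0.0920), the sex gene score (adjusted p = 0.119) or the number series as covariates (adjusted p = 0.0600), with the stricter filter or with only these 2 groups in the fit. Adora2a was lost with the tissue scores (adjusted p = 0.0799), the sex gene score (adjusted p = 0.119) and the stricter filter, Il33 with the sex gene score, Sgk1 with the sex gene score, the number series, the stricter filter and the 2 groups alone, and Anxa5 with the 2 groups alone and without a filter. All libraries had the pattern of male mice, so losses with the sex gene score show no effect of sex.

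**Figure D3:**
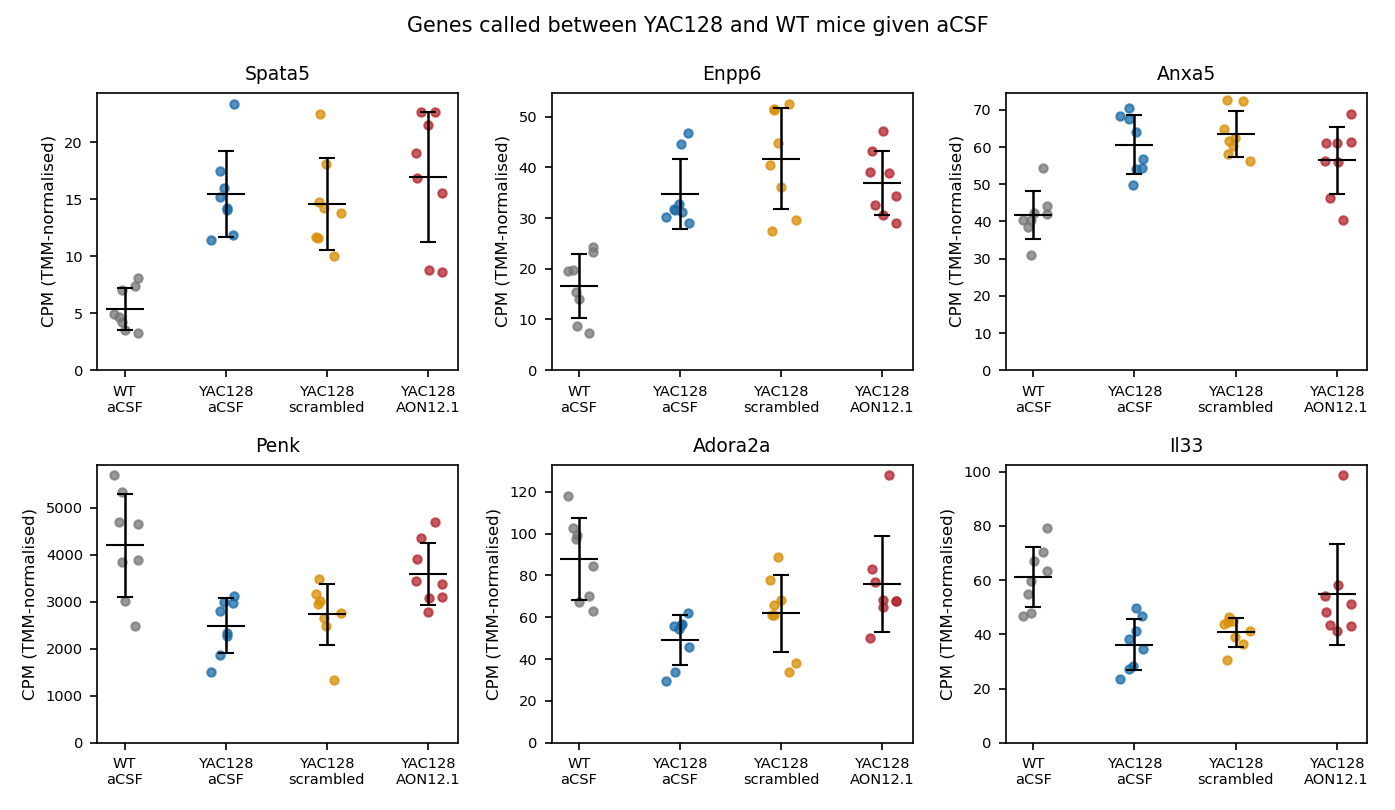
Level in CPM (y axis, from 0) of Spata5, Enpp6, Anxa5, Penk, Adora2a and Il33 in each library, by group (x axis), with the bar at the group mean ± SD, n = 8. Penk averages 2488 CPM in YAC128 aCSF and 4201 CPM in WT aCSF mice, and Spata5 averages 15.4 and 5.39 CPM.

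Of 37 gene lists, 13 were called for genotype with the preset correlation, 2 higher and 11 lower, and 0 with an estimated correlation. Of 100 splits of these 16 libraries into sets of 8, the real one included, 8 called at least as many lists with the preset correlation. Striatal projection neuron genes were lower as a list (45 members tested, 42 with a lower value, adjusted p = 1.15e-09 by camera), but adjusted p = 0.394 with an estimated correlation. Of these, 2 members fell over all genes and 2 adjusted over the list alone, Penk and Adora2a. Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, had a log2 fold change of -0.50 ± 0.19 (adjusted p = 0.289), and Drd2 one of -0.41 (adjusted p = 0.372). The indirect pathway list (8 members, 7 lower, 2 called over all genes and 2 adjusted over the list alone) had adjusted p = 0.000116, and adjusted p = 0.0547 with an estimated correlation. The direct pathway list (10 members) was not called (adjusted p = 0.182), with Drd1 at -0.16 (adjusted p = 0.746) and Pdyn at -0.27 (adjusted p = 0.459). Interneuron genes (12 members) were lower at adjusted p = 0.0460 (adjusted p = 0.213 with an estimated correlation), with Sst at -0.39 and Pvalb at -0.46. Cortical excitatory neuron genes (15 members) were lower at adjusted p = 0.0441 (adjusted p = 0.659 with an estimated correlation). Neither of the last 2 lists had a member called over all genes, and 1 interneuron gene fell adjusted over the list alone. Without YAC128 aCSF replicate 2 the interneuron (adjusted p = 0.0576) and cortical lists (adjusted p = 0.0548) were no longer called, nor without replicate 4 of that group (adjusted p = 0.0501 and 0.114).

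Among glial and signalling lists, astrocyte genes were lower (20 members, 17 with a lower value, adjusted p = 7.48e-05, and adjusted p = 0.147 with an estimated correlation). None was called over all genes, and 4 fell adjusted over the list alone, among them the glutamate transporter Slc1a2 (-0.37 ± 0.08), the aldolase Aldoc (-0.32) and the protease Htra1 (-0.38). Interferon response genes were higher (10 members, 8 with a higher value, adjusted p = 0.000196, and adjusted p = 0.0547 with an estimated correlation). Of them 0 were called over all genes and 4 rose adjusted over the list alone, among them Ifitm3 at 0.60 ± 0.15, a membrane protein that restricts virus entry. Glucocorticoid response genes were lower (15 members, 11 with a lower value, adjusted p = 0.000797, and adjusted p = 0.0547 with an estimated correlation), with 1 called over all genes, Sgk1, and 5 adjusted over the list alone. Choroid plexus genes, which mark tissue outside the striatum, were higher (5 members, all with a higher value, adjusted p = 0.0348, and adjusted p = 0.394 with an estimated correlation). Ttr, the transthyretin of choroid plexus, had a log2 fold change of 4.01 ± 0.92 (adjusted p = 0.0671), with 3191 CPM in YAC128 aCSF replicate 4 and at most 151 CPM in the other libraries of that group. Without that replicate the choroid plexus list had adjusted p = 0.380, and without WT replicate 1 adjusted p = 0.0590.

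Metabolic and housekeeping lists were lower with small medians. Oxidative phosphorylation genes (50 members, 47 lower, adjusted p = 4.85e-09, and adjusted p = 0.213 with an estimated correlation) included the respiratory chain genes Ndufs7 (-0.31) and Uqcrc1 (-0.24). Glycolysis genes (18 members, 17 lower, 3 adjusted over the list alone) had adjusted p = 5.55e-05, and adjusted p = 0.213 with an estimated correlation, with the lactate dehydrogenase subunit Ldhb at -0.29. Ribosomal protein genes (53 members, 41 lower) had adjusted p = 0.000665, and adjusted p = 0.575 with an estimated correlation, with Rpl28 at -0.26. Synaptic vesicle genes (24 members, 22 lower) had adjusted p = 0.000118, and adjusted p = 0.320 with an estimated correlation, with Cplx2 at -0.30. Proteasome genes (27 members, 23 lower) had adjusted p = 0.000319, and adjusted p = 0.147 with an estimated correlation, with Psma4 at -0.31 and Psmc4 at -0.28. None of these lists had a member called over all genes. The no-feature share was 6.12 points higher in the same YAC128 libraries, and 8 lists were called with it as a covariate.

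AON12.1 was set against the scrambled oligonucleotide to separate its sequence from an oligonucleotide of the same kind. The gene with the smallest p was 1110038B12Rik (ENSMUSG00000092203, chromosome 17), a noncoding host gene of small nucleolar RNAs, which rose from 19.4 ± 5.58 to 103 ± 15.8 CPM (SD, n = 8 each; 2.39 ± 0.15, adjusted p = 5.17e-15). C4b (ENSMUSG00000073418, chromosome 17), a component of the complement cascade, rose from 53.1 ± 11.6 to 122 ± 33.1 CPM (1.19 ± 0.15, adjusted p = 6.67e-06). The linker histone gene Hist1h1c (1.16 ± 0.16, adjusted p = 3.45e-05) and the integrin subunit gene Itgb4 (0.84 ± 0.14, adjusted p = 0.00106) rose as well. Nrip3 fell by 0.72 on the log2 scale (SE 0.13, adjusted p = 0.00311) and the sodium leak channel gene Nalcn by 0.71 (SE 0.14, adjusted p = 0.0157).

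Genes expressed in oligodendrocytes were among the other calls. Qdpr, a dihydropteridine reductase, rose from 218 to 305 CPM (0.48 ± 0.09, adjusted p = 0.00892), Gsn, the actin-severing protein gelsolin, from 63.0 to 99.1 CPM (0.63 ± 0.13, adjusted p = 0.0170), and Trf, transferrin, from 616 to 905 CPM (0.55 ± 0.12, adjusted p = 0.0309). Gas5, another noncoding host of small nucleolar RNAs, rose by 0.74 ± 0.16 (adjusted p = 0.0308), and Dcdc2a and Gab1 rose by 0.81 each (adjusted p = 0.00892 and 0.0329). Alkbh6 fell by 0.50 and Rnf157 by 0.38. With AON12.1 against aCSF, 1110038B12Rik, C4b, Hist1h1c, Itgb4, Nalcn, Gsn and Alkbh6 were called as well. Qdpr, Trf, Gas5, Dcdc2a, Gab1, Rnf157 and Nrip3 were not, so for these it is not settled which oligonucleotide group moved from aCSF. In all, 15 genes were called between AON12.1 and scrambled, 10 higher and 5 lower, with 774 at an unadjusted p under 0.05, 20 calls in DESeq2 and 13 in voom. The named calls kept their sign within both number series, which is no independent test, since the same libraries gave the calls. AON12.1 replicate 2 had higher Qdpr (439 CPM) and Gsn (154 CPM) than the other libraries of its group, whose highest values were 324 and 114 CPM. C4b counts are uncertain where reads match its copy C4a, as are those of Hist1h1c within its histone family. With only these 2 groups in the fit 7 genes were called, and Alkbh6, Gab1, Gas5, Gsn, Nalcn, Qdpr, Rnf157 and Trf were not among them. Leaving out 1 library at a time ended the call of Trf in 11 of 16 fits, of Gab1 and Rnf157 in 10, of Gas5 in 8, of Alkbh6 in 4, of Gsn in the fit without AON12.1 replicate 2 and of Nalcn in that without AON12.1 replicate 8. Gab1 and Gas5 were also lost in voom and, with Rnf157, with the cortex and choroid plexus scores as covariates, and Gab1 and Rnf157 without a filter.

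Against the scrambled group, 6 lists were called, 4 higher and 2 lower, and 0 with an estimated correlation. Of 100 splits of these 16 libraries into sets of 8, the real one included, 58 called at least as many lists with the preset correlation. A small adjusted p with the preset correlation thus does not by itself set a list apart here. Striatal projection neuron genes were higher (40 of 45 with a higher value, adjusted p = 9.14e-12), but adjusted p = 0.477 with an estimated correlation, and 0 members were called over all genes or adjusted over the list alone. Penk had a log2 fold change of 0.40 ± 0.16 (adjusted p = 0.573) and Ppp1r1b one of 0.29 (adjusted p = 0.797). Scrambled replicate 5 had Penk at 1340 CPM and Six3 at 205 CPM, against at least 2488 and 377 CPM in the other libraries of its group. AON12.1 replicate 2 had Adora2a at 128 CPM and Hpca at 2497 CPM, against at most 83.2 and 1617 CPM in the others of its group. The direct pathway list was higher (9 of 10 with a higher value, adjusted p = 0.000429, and adjusted p = 0.127 with an estimated correlation), and 4 members rose adjusted over the list alone, among them Drd1 at 0.42, the dynorphin precursor Pdyn at 0.42 and the substance P precursor Tac1 at 0.43. The indirect pathway list was higher at adjusted p = 0.0331 (adjusted p = 0.418 with an estimated correlation), with Adora2a at 0.27 and Drd2 at 0.31, and was not called without AON12.1 replicate 2 (adjusted p = 0.102) or scrambled replicate 5 (adjusted p = 0.0773). Reactive astrocyte genes (8 members, 1 called over all genes, 3 adjusted over the list alone) had adjusted p = 0.000429, and adjusted p = 0.0684 with an estimated correlation. That list holds C4b beside Serpina3n (0.66 ± 0.25, adjusted p = 0.501) and Gfap (0.30 ± 0.18, adjusted p = 0.762), and without C4b it was not called (adjusted p = 0.160).

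Cholesterol synthesis genes were lower with AON12.1 than with the scrambled oligonucleotide (21 members, 18 with a lower value, adjusted p = 0.00205, and adjusted p = 0.127 with an estimated correlation), with Sqle at -0.37, Dhcr7 at -0.33 and Pmvk at -0.30. Cortical excitatory neuron genes were lower (13 of 15, adjusted p = 0.0281, and adjusted p = 0.727 with an estimated correlation), with Neurod2 at -1.18 ± 0.53 (adjusted p = 0.639). In scrambled replicate 5 Neurod2 stood at 297 CPM and Lmo4 at 614 CPM, against at most 120.3 and 451 CPM in the other libraries of that group, and without that replicate the cortical list was not called (adjusted p = 0.528). No cholesterol or cortical gene was called over all genes. The mean level of the projection neuron list per library was 0.26 higher on the log2 scale with AON12.1 than with the scrambled oligonucleotide (exact permutation test, two-sided, p = 0.0625, adjusted p = 0.319 over 48 tests).

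Against aCSF, YAC128 mice given AON12.1 had higher levels of a complement gene, of microglial genes and of an astrocyte gene. 1110038B12Rik rose from 17.9 ± 5.06 to 103 ± 15.8 CPM (SD, n = 8 each; 2.53 ± 0.15, adjusted p = 9.28e-16) and C4b from 38.7 to 122 CPM (1.64 ± 0.16, adjusted p = 3.20e-09). Prmt8 (ENSMUSG00000030350, chromosome 6), a brain arginine methyltransferase, rose from 83.2 ± 18.6 to 152 CPM (0.86 ± 0.12, adjusted p = 7.44e-05). The microglial genes Lyz2, a lysozyme (1.29 ± 0.21, adjusted p = 0.00118), Tyrobp, a signalling adaptor (0.79 ± 0.13, adjusted p = 0.00122), Cd52 (1.55 ± 0.27, adjusted p = 0.00137) and Laptm5 (0.57 ± 0.12, adjusted p = 0.0206) rose. Gfap, the astrocyte intermediate filament, rose from 46.3 ± 12.2 to 79.8 ± 18.1 CPM (0.77 ± 0.18, adjusted p = 0.0410).

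Further calls against aCSF were higher values of Hist1h1c (0.92 ± 0.15), of the lipocalin Apod (0.55 ± 0.11, 517 against 353 CPM), of Gsn (0.64 ± 0.13), Shisa9 (0.59 ± 0.11) and Mras (0.41). Nalcn fell by 0.82 (SE 0.14, adjusted p = 0.00128), Bend6 by 0.71 (SE 0.13, adjusted p = 0.00307), Dmrtc1a by 1.10 and Ints6l by 1.05. Hypk (-0.71), Dzip3 (-0.76), Adssl1 (-0.68), Mettl26 (-0.61) and Alkbh6 (-0.46) were also called lower. In all, 33 genes were called, 23 higher and 10 lower, with 1234 at an unadjusted p under 0.05, 90 calls in DESeq2 and 35 in voom. DESeq2 gave 13 of the 33 no adjusted p. The named calls kept their sign within both number series, again among the libraries that gave the calls. Leaving out 1 library at a time ended the call of Gfap in 12 of 16 fits, of Alkbh6 in 6, of Laptm5 and Adssl1 in 5, of Ints6l in 2 and of Dmrtc1a in the fit without YAC128 aCSF replicate 3. With the no-feature share as a covariate the adjusted p of Gfap was 0.0616, and its call was also lost with the stricter filter and with the number series, sex gene or tissue scores as covariates. Alkbh6 and Laptm5 were lost with the tissue scores, Adssl1 with the sex gene score and Alkbh6 without a filter. With only these 2 groups in the fit 24 genes were called, and Laptm5, Gsn, Mras, Adssl1 and Alkbh6 were not among them. Lyz2 counts are uncertain where reads match its copy Lyz1.

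**Figure D4:**
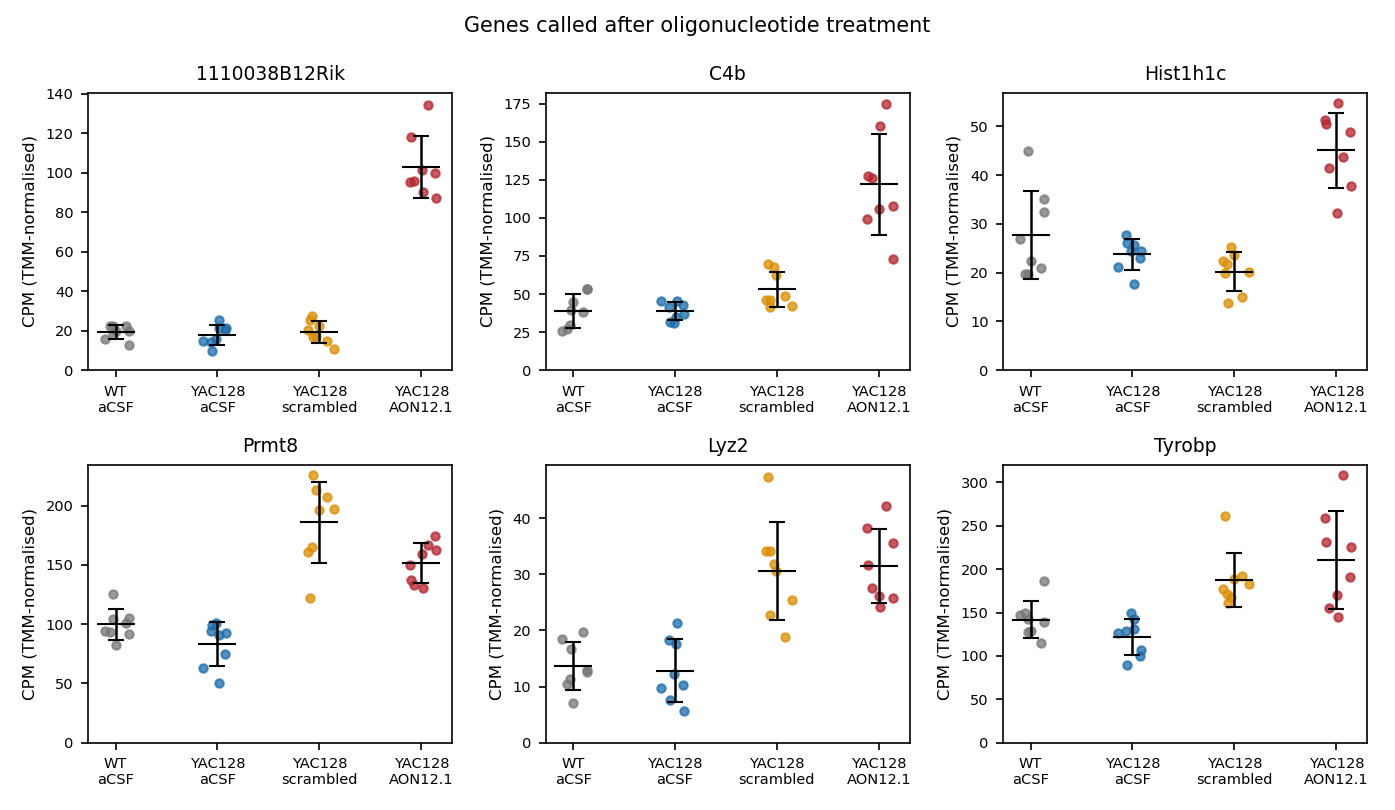
Level in CPM (y axis, from 0) of 1110038B12Rik, C4b, Hist1h1c, Prmt8, Lyz2 and Tyrobp in each library, by group (x axis), with the bar at the group mean ± SD, n = 8. 1110038B12Rik averages 103 CPM with AON12.1 and 19.4 CPM with the scrambled oligonucleotide, while Prmt8 averages 152 and 186 CPM in these groups and 83.2 CPM in YAC128 aCSF.

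Lists called against aCSF numbered 17, with 13 higher and 4 lower, and 2 with an estimated correlation. Those 2 were the reactive astrocyte list (8 members, 7 higher, adjusted p = 1.34e-06, and adjusted p = 0.00287 with an estimated correlation) and the complement list (7 members, 5 higher, adjusted p = 1.34e-06, and adjusted p = 0.00287 with an estimated correlation). C4b belongs to both, and with C4b taken out each had adjusted p = 0.150 with an estimated correlation, against 0.0127 and 0.0195 with the preset one. In the reactive astrocyte list C4b and Gfap rose over all genes and 2 adjusted over the list alone. In the complement list C4b rose over all genes and 3 adjusted over the list alone, among them C1qb, a chain of complement C1q (0.46 ± 0.11, adjusted p = 0.0531 over all genes). Genes of disease-associated microglia (14 members, 13 higher, Tyrobp and Lyz2 called over all genes, 2 adjusted over the list alone) had adjusted p = 3.55e-06, and adjusted p = 0.108 with an estimated correlation. Homeostatic microglia genes (17 members, Laptm5 called over all genes, 4 adjusted over the list alone) had adjusted p = 0.00681, and adjusted p = 0.171 with an estimated correlation. MHC class I genes (5 members, 3 adjusted over the list alone, H2-D1 at 0.37 and B2m at 0.36) had adjusted p = 0.0283, and adjusted p = 0.171 with an estimated correlation, and were not called without YAC128 aCSF replicate 2 (adjusted p = 0.0698) or 4 (adjusted p = 0.142) or AON12.1 replicate 2 (adjusted p = 0.0768).

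Striatal projection neuron genes were higher with AON12.1 than with aCSF (44 of 45 with a higher value, adjusted p = 2.40e-18, and adjusted p = 0.150 with an estimated correlation). Over all genes 0 members were called, and 22 rose adjusted over the list alone, among them Hpca at 0.63 ± 0.16, a neuronal calcium sensor, Tac1 at 0.56 ± 0.14, Penk at 0.53 ± 0.16 and Adora2a at 0.60 ± 0.18. In AON12.1 replicate 2 Hpca stood at 2497 CPM, Adora2a at 128 CPM and Chrm1 at 251 CPM, against at most 1617, 83.2 and 206 CPM in the others of its group, and without it the list had adjusted p = 1.28e-15. The direct (adjusted p = 0.00137, 3 adjusted over the list alone) and indirect pathway lists (adjusted p = 0.00119, 2 adjusted over the list alone) were higher too, but had adjusted p = 0.150 and adjusted p = 0.124 with an estimated correlation. The mean level of the projection neuron list per library was 0.37 higher on the log2 scale (exact permutation test, two-sided, p = 0.00777, adjusted p = 0.186 over 48 tests). Postsynaptic glutamate genes (25 members, 7 adjusted over the list alone) had adjusted p = 1.34e-06, and adjusted p = 0.150 with an estimated correlation, with the kinase subunit Camk2a at 0.41 and the scaffold Dlg4 at 0.33. Voltage-gated ion channel genes (33 members, 4 adjusted over the list alone) had adjusted p = 0.00119, and adjusted p = 0.171 with an estimated correlation, with Kcnq3 at 0.43. None of these genes was called over all genes.

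Other lists higher against aCSF were cortical excitatory neuron genes (adjusted p = 0.00454, and adjusted p = 0.410 with an estimated correlation), with Lamp5 at 0.38 and Lmo4 at 0.32, and ribosomal protein genes (adjusted p = 7.77e-05, and adjusted p = 0.336 with an estimated correlation), with Rps3 at 0.29. Genes of the mitochondrial genome (9 members, 2 adjusted over the list alone) were higher at adjusted p = 0.00463 (adjusted p = 0.330 with an estimated correlation), with mt-Nd5 at 0.36 and mt-Nd2 at 0.30. Lower lists were thalamus markers (9 members, adjusted p = 0.0277, and adjusted p = 0.410 with an estimated correlation), with the glutamate transporter gene Slc17a6 at -1.12 and Calb2, calretinin, at -1.09, and septum, hypothalamus and pallidum markers (12 members, adjusted p = 0.00564, and adjusted p = 0.330 with an estimated correlation), with Oxt at -1.55. In YAC128 aCSF replicate 2 Calb2 stood at 169 CPM and Slc17a6 at 67.5 CPM, against at most 73.9 and 18.7 CPM in the other libraries of that group. Without that replicate the thalamus list had adjusted p = 0.135 and the mitochondrial one adjusted p = 0.0650. Heat shock genes (20 members, Dnajb1 at -0.63 adjusted over the list alone) were lower at adjusted p = 0.00582 (adjusted p = 0.228 with an estimated correlation). Dnajb1 stood at 234 CPM in YAC128 aCSF replicate 2, against at most 137 CPM in the other libraries of that group, and without that replicate the heat shock list had adjusted p = 0.0152. Cholesterol synthesis genes (2 adjusted over the list alone) were lower at adjusted p = 0.0091 (adjusted p = 0.150 with an estimated correlation), with Sqle at -0.54 and Pmvk at -0.43.

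The scrambled oligonucleotide, which lacks the target sequence, was compared with aCSF to show what an oligonucleotide of this kind does. Prmt8 rose from 83.2 ± 18.6 to 186 ± 34.2 CPM (SD, n = 8 each; 1.16 ± 0.12, adjusted p = 1.20e-07). Lyz2 rose from 12.8 to 30.6 CPM (1.28 ± 0.21, adjusted p = 0.00222), and Klk6, a secreted serine protease of oligodendrocytes, from 5.86 to 18.5 CPM (1.66 ± 0.28, adjusted p = 0.00222). The complement chains C1qb (0.58 ± 0.11, adjusted p = 0.0182) and C1qa (0.62 ± 0.12, adjusted p = 0.0190) and the adaptor Tyrobp (0.62 ± 0.13, adjusted p = 0.0443) rose. Rps26, Scrt1 and Kcnh1 rose by 0.49, 0.50 and 0.64 on the log2 scale (SE 0.10, 0.11 and 0.14, adjusted p = 0.0443, 0.0472 and 0.0472).

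These 9 genes were all of the calls, each higher, beside 1050 genes at an unadjusted p under 0.05, with 23 calls in DESeq2 and 8 in voom. DESeq2 gave 3 of the 9 no adjusted p. C4b had a log2 fold change of 0.44 ± 0.17 (adjusted p = 0.373), 1110038B12Rik one of 0.14 (adjusted p = 0.830), and Gfap one of 0.48 ± 0.18 (adjusted p = 0.388). All 9 kept their sign within both number series, again among the libraries that gave the calls. Leaving out 1 library at a time, Prmt8, Lyz2 and Klk6 stayed called in 16 of 16 fits, while the call ended in 14 fits for Scrt1, 13 for Kcnh1 and Tyrobp, 10 for Rps26, 5 for C1qa and 4 for C1qb. With the number series as a covariate 5 genes were called, and Kcnh1, Rps26, Scrt1 and Tyrobp were not among them. With the cortex and choroid plexus scores as covariates 4 were called, and C1qb (0.57, adjusted p = 0.0586) was lost beside these. Kcnh1, Rps26 and Tyrobp were lost with the no-feature share, Kcnh1, Rps26 and Scrt1 with only these 2 groups in the fit, Kcnh1 and Scrt1 in voom and without a filter, and Scrt1 with the stricter filter. The share of mitochondrial counts was 0.471 percentage points higher with the scrambled oligonucleotide (exact permutation test, two-sided, p = 0.00451, adjusted p = 0.186 over 48 tests).

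For the scrambled oligonucleotide, 14 lists were called against aCSF, 13 higher and 1 lower, and 0 with an estimated correlation. With the cortex and choroid plexus scores as covariates 7 lists were called, and with the no-feature share 9. Complement genes (7 members, C1qa and C1qb called over all genes, 4 higher and 1 lower adjusted over the list alone) had adjusted p = 0.00241, and adjusted p = 0.250 with an estimated correlation. Disease-associated microglia genes (Lyz2 and Tyrobp called over all genes, 3 adjusted over the list alone) had adjusted p = 3.70e-05, and adjusted p = 0.250 with an estimated correlation. Homeostatic microglia genes (3 adjusted over the list alone, Laptm5 at 0.45) had adjusted p = 0.00785, and adjusted p = 0.264 with an estimated correlation. The reactive astrocyte list was not called (adjusted p = 0.129). Cortical excitatory neuron genes, all 15 with a higher value and 2 adjusted over the list alone, had adjusted p = 3.17e-08, and adjusted p = 0.250 with an estimated correlation, with Neurod2 at 1.39 ± 0.53 (adjusted p = 0.383) and Mef2c at 0.56. In scrambled replicate 5 Neurod2 stood at 297 CPM, against at most 120.3 CPM in the other libraries of that group. Septum, hypothalamus and pallidum markers were lower (adjusted p = 0.00115, and adjusted p = 0.311 with an estimated correlation), with Oxt at -1.94 and Baiap3 at -0.67, which fell adjusted over the list alone. The mean level of the cortical list per library was 0.68 higher on the log2 scale (exact permutation test, two-sided, p = 0.0440, adjusted p = 0.319 over 48 tests).

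Neuronal activity and synapse lists were higher with the scrambled oligonucleotide than with aCSF, without a member called over all genes. Immediate early genes (23 members) had adjusted p = 0.00241 (adjusted p = 0.406 with an estimated correlation), with Egr3 at 0.68. Postsynaptic glutamate genes had adjusted p = 3.70e-05 (adjusted p = 0.264 with an estimated correlation), with Camk2a at 0.47, Homer1 at 0.40 and Grin2a at 0.50. Synaptic vesicle genes had adjusted p = 0.000928 (adjusted p = 0.406 with an estimated correlation), with Cplx2 at 0.33 and Bsn at 0.39. Striatal projection neuron genes had adjusted p = 0.00785 (adjusted p = 0.661 with an estimated correlation), with Penk at 0.14 (adjusted p = 0.819). Voltage-gated ion channel genes had adjusted p = 0.0149 (adjusted p = 0.406 with an estimated correlation). Oxidative phosphorylation (adjusted p = 0.00198, and adjusted p = 0.543 with an estimated correlation) and glycolysis genes (adjusted p = 0.0306, and adjusted p = 0.543 with an estimated correlation) were higher with small medians, with Cox7c at 0.38 and Hk1 at 0.23. Genes of the mitochondrial genome had adjusted p = 0.000459 (adjusted p = 0.264 with an estimated correlation), with mt-Co1 at 0.21. Ribosomal protein genes had adjusted p = 0.00785 (adjusted p = 0.582 with an estimated correlation), with Rps14 at 0.35. Without YAC128 aCSF replicate 2 the projection neuron (adjusted p = 0.558), ion channel (adjusted p = 0.0740) and glycolysis lists (adjusted p = 0.138) were not called. The glycolysis list was also lost without YAC128 aCSF replicate 4 (adjusted p = 0.132) and, with the synaptic vesicle list, without scrambled replicate 5 (adjusted p = 0.0701 and 0.0645).

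The oligonucleotide groups were also compared with WT aCSF, to show how far treated YAC128 mice stood from WT, and these comparisons share the WT libraries with each other and with the genotype comparison. With AON12.1, Spata5 rose by 1.57 ± 0.25 (adjusted p = 0.000539), Enpp6 by 1.15 ± 0.19 (adjusted p = 0.000886), Prmt8 by 0.60 ± 0.12 (adjusted p = 0.00772), C4b by 1.63 ± 0.16 (adjusted p = 4.65e-09) and Apod by 0.69 ± 0.11 (adjusted p = 0.000539). Lower with AON12.1 than in WT were Dmrtc1a (-1.32 ± 0.23, adjusted p = 0.00162), Bend6 (-0.70 ± 0.13, adjusted p = 0.00443), Nrip3 (-0.66 ± 0.13, adjusted p = 0.00479), Nalcn (-0.70 ± 0.14, adjusted p = 0.00783), Alkbh6 (-0.48) and Rnf157 (-0.36), the last not called without WT replicate 5. Alkbh6 and Rnf157 were also lost with only these 2 groups in the fit, and Rnf157 without a filter. With the scrambled oligonucleotide, Spata5 rose by 1.38 ± 0.25 (adjusted p = 0.00477), Enpp6 by 1.35 ± 0.19 (adjusted p = 3.97e-05), Prmt8 by 0.90 ± 0.12 (adjusted p = 3.28e-05) and Anxa5 by 0.60 ± 0.11 (adjusted p = 0.00475), and Qdpr fell by 0.65 (SE 0.09, adjusted p = 3.97e-05). In all, 60 genes were called with AON12.1 against WT, 25 higher and 35 lower, and 18 with the scrambled oligonucleotide, 14 higher and 4 lower. At an unadjusted p under 0.05 there were 1546 and 1047 genes. DESeq2 called 104 and 39 genes and voom 85 and 39.

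Of the 37 lists, 16 were called with AON12.1 against WT, 8 higher and 8 lower, and 4 with an estimated correlation. Those 4, all higher, were reactive astrocyte genes (8 members, 2 called over all genes, adjusted p = 2.70e-07, and adjusted p = 0.00156 with an estimated correlation), complement genes (7 members, 1 called over all genes, C4b, adjusted p = 1.13e-05, and adjusted p = 0.00387 with an estimated correlation), interferon response genes (10 members, adjusted p = 0.000423, and adjusted p = 0.0456 with an estimated correlation) and MHC class I genes (5 members, adjusted p = 0.00101, and adjusted p = 0.0456 with an estimated correlation). Ifitm3 (0.73 ± 0.15, adjusted p = 0.00783) and B2m (0.68 ± 0.15, adjusted p = 0.0209) were among the members called over all genes. Leaving out 1 library at a time ended the call of B2m in 4 of 16 fits and that of Ifitm3 in 0. With C4b taken out of the lists, 0 of the 4 passed with an estimated correlation, at adjusted p = 0.158 for complement genes and adjusted p = 0.0740 for each of the others. C4b belongs to the reactive astrocyte and complement lists. The adjustment runs over all lists together, so the adjusted p of a list can move when only other lists change. The values for interferon response and MHC class I genes thus do not show that C4b carried them. With the scrambled oligonucleotide against WT 16 lists were called too, 8 higher and 8 lower, and 0 with an estimated correlation.

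Whether treatment moved the genes that differed most by genotype toward their WT level was asked with 200 genes. AON12.1 against scrambled gave a median signed log2 fold change of 0.05 (adjusted p = 0.890 by limma's fry over 7 settings), and 39% of the genes lay toward WT. Against aCSF, with the control split, the mean over 70 splits was -0.07 for AON12.1 (SD 0.0662, range -0.207 to 0.0815) and -0.10 for the scrambled oligonucleotide (SD 0.0548). With the no-feature share as a covariate these means were 0.00906 and 0.0200, no longer toward WT. Splits that share libraries are not independent, so no p-value was drawn from them. Over the called genotype genes alone, AON12.1 against scrambled gave -0.20 (adjusted p = 0.0460 over the same settings), and none of the 8 was called by itself. That value did not pass without AON12.1 replicate 2 (-0.14, adjusted p = 0.1203), without scrambled replicate 5 (-0.16, adjusted p = 0.143) or without both (-0.12, adjusted p = 0.361), each put in its place among the settings. Il33 stood at 98.7 CPM in that AON12.1 library, against at most 58.2 CPM in the others of its group, and Penk at 1340 CPM in that scrambled library, against at least 2488 CPM. Penk (0.40 ± 0.16), Il33 (0.38), Adora2a (0.27), Sgk1 (0.21), Enpp6 (-0.19) and Anxa5 (-0.16) had values toward WT, and Spata5 (0.19) and NM_001388492 (0.11) away from it.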

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

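In 456 sets of 8 libraries, covering 111 genes and the library measures, the highest or lowest library was compared with the other 7 by the gap criterion of Dixon, and 49 sets had a library apart where about 23 are due by chance. The group difference in the no-feature share was singled out after it was seen. No explanation is offered for the values in this part.

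AON12.1 replicate 2 stood apart most often. It had 658930 gene counts, against 934200 to 1097000 in the other libraries of its group. The myelin gene Mbp was high, at 4018 CPM against 1853 to 2217. So were the oligodendrocyte-expressed genes Apod (806 against 423 to 546), Gsn (154 against 78.1 to 114), Qdpr (439 against 248 to 324) and the cytokine Il33 (98.7 against 41.3 to 58.2). Its neuronal genes Adora2a (128 against 50.2 to 83.2), Hpca (2497 against 1093 to 1617), Chrm1 (251 against 169 to 206), Pvalb (59.9 against 13.2 to 33.3) and Shisa9 (102 against 62.2 to 75.8) and the ribosomal gene Rps3 (914 against 594 to 727) were also above the rest.

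YAC128 aCSF replicate 2 had high Calb2 (169 CPM against 42.1 to 73.9), Slc17a6 (67.5 against 9.38 to 18.7), Dnajb1 (234 against 66.6 to 137) and Mettl26 (88.7 against 62.0 to 73.9), and low Mbp (1624 against 2246 to 2647). YAC128 aCSF replicate 4 had Ttr at 3191 CPM against 3.75 to 151 and Enpp2 at 596 against 102 to 142, both genes of choroid plexus. YAC128 aCSF replicate 8 had Neurod2 at 126 CPM against 4.25 to 58.8 and Mef2c at 236 against 85.7 to 141. YAC128 aCSF replicate 3 had Pde10a at 330.4 CPM and Dmrtc1a at 28.9 CPM, and replicate 5 had Adssl1 at 53.2 CPM, all above the others of the group.

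Scrambled replicate 5 had high cortical genes, with Neurod2 at 297 CPM against 15.3 to 120.3 and Lmo4 at 614 against 379.9 to 451, together with Chrm1 (274) and Hk1 (332). Its striatal genes Penk (1340 CPM against 2488 to 3488) and Six3 (205 against 377 to 480.3) were below the others. Scrambled replicate 3 had high Tyrobp (261 CPM) and Cd52 (17.9 CPM), and replicate 2 high Laptm5 (94.2 CPM). Scrambled replicate 7 was high in Cox7c (606 CPM), replicate 6 in mt-Rnr1 (4351 CPM) and replicate 8 in Serpina3n (31.8 CPM).

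WT replicate 1 had a no-feature share of 30.2% against 16.3% to 19.2% in the other WT libraries, with Htt at 129.5 CPM, Plxdc1 at 36.5 CPM and Scrt1 at 114 CPM, all above them. WT replicate 4 was high in Apod (469 CPM) and replicate 8 in Kcnip3 (149 CPM), while replicate 7 was low in mt-Co1 (552 CPM) and replicate 3 in Qdpr (298 CPM). Among AON12.1 libraries, replicate 3 was low in Ifitm3 (32.9 CPM) and replicate 7 in Mras (174 CPM), and replicate 4 was high in mt-Rnr1 (4517 CPM), replicate 5 in Pmvk (87.4 CPM) and replicate 1 in Slc2a3 (133 CPM). In the summary lines, which no gene comparison uses, YAC128 aCSF exceeded WT aCSF by 6.12 percentage points in the no-feature share (exact permutation test, two-sided, p = 0.0292, adjusted p = 0.319 over 48 tests).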

How the results depend on the processing

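The settings with the no-feature share, the libraries with a share up to 25%, the lists and the movement without single libraries and the lists without C4b were chosen after the results were seen. RLE size factors and leaving out mitochondrial genes moved no count of called genes by over 1.5 times. Htt, fitted with RLE, DESeq2, voom, only the 2 groups and each covariate alone (number series, sex genes, tissue scores, no-feature share), was not called in the 4 main comparisons, and DESeq2 gave no adjusted p for it for genotype. No called named gene changed sign, and DESeq2's own filter left many of them without an adjusted p. Up to 4 uncalled named genes changed sign in a comparison, most for genotype with the no-feature covariate. The largest shift of the median of all genes was 0.05 in log2. No library was shallow enough for the planned exclusion by depth, so that setting gave no value. No paired analysis was possible because the labels pair no animals across groups. The cause of the moves below was not tested unless stated.

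Genes called for genotype, 8 in the report, numbered 21 without a filter, 2 with the stricter filter, 54 in DESeq2 (3 higher), 20 in voom, 4 with the sex gene score, 2 in each number series alone, 4 with the no-feature share, 4 with it and tissue scores, and 1 among libraries up to 25%. For AON12.1 against scrambled, 15 in the report, they were 9 with the stricter filter, 7 with the 2 groups alone, 1 in series 18, 5 in series 19 and 8 up to 25%. For AON12.1 against aCSF, 33 in the report, they were 57 without a filter, 90 in DESeq2, 276 in series 18 (2 against 4 libraries), 2 in series 19 and 6 up to 25%. There the no-feature share differed by -10.9 points in series 18 and 3.48 in series 19. For scrambled against aCSF, 9 in the report, they were 14 without a filter, 5 with the stricter filter, 23 in DESeq2, 5 with the 2 groups alone, 5 with the number series as covariate, 4 with cortex and choroid plexus scores, 1 in each series alone, 5 with the no-feature share and tissue scores, and 1 up to 25%. Against WT, AON12.1 gave 104 in DESeq2, 3 in series 18, 26 in series 19 and 33 up to 25%, instead of 60. The scrambled group gave 33 without a filter, 39 in DESeq2, 39 in voom, 3 in series 18, 4 in series 19 and 28 with the no-feature share, instead of 18. Fewer libraries enter the single series and the libraries up to 25%, of which 7 were WT, 3 YAC128 aCSF, 5 AON12.1 and 7 scrambled.

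Leaving out each library gave 3 to 142 genes for genotype, 10 to 17 for AON12.1 against scrambled, 26 to 73 against aCSF, 3 to 13 for scrambled against aCSF, 49 to 97 for AON12.1 against WT and 10 to 27 for scrambled against WT. For genotype, 142 came without WT replicate 1 and 27 without YAC128 aCSF replicate 8, while 3 came without WT replicate 2 or 6 or aCSF replicate 6, 4 without WT replicate 3 or aCSF replicate 2, 5 or 7, and 5 without WT replicate 8. For AON12.1 against aCSF, 73 came without aCSF replicate 8 and 61 without AON12.1 replicate 7. For scrambled against aCSF, 3 came without aCSF replicate 2 or 3 or scrambled replicate 8, 4 without aCSF replicate 4 or 6, and 5 without scrambled replicate 1 or 7. Against WT, AON12.1 gave 97 without its replicate 5, and the scrambled group 10 without WT replicate 3 or 8.

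With an estimated correlation the lists called were 0 for genotype, 0 for AON12.1 against scrambled, 2 for AON12.1 against aCSF and 0 for scrambled against aCSF, in place of 13, 6, 17 and 14, and 0 in both AON12.1 comparisons with C4b taken out as well. With the no-feature share, 8 lists were called for genotype and 9 for scrambled against aCSF, and with cortex and choroid plexus scores 7 for the latter. The number of lists called without WT replicate 1, aCSF replicate 2 or 4, AON12.1 replicate 2 or scrambled replicate 5 stayed within 1.5 times. The movement of genotype genes, 0.05 for AON12.1 against scrambled, was reversed over the called genes alone (-0.20), which is a set of 8, and also without AON12.1 replicate 2 (-0.136) or scrambled replicate 5 (-0.163), without passing the adjusted threshold. For AON12.1 against aCSF it went from -0.07 to 0.01 (0.00906) with the no-feature share, and for scrambled against aCSF from -0.10 to 0.02 (0.0200), or to -0.04 (-0.0403) with tissue scores. At the depth of these libraries, 1.5-fold changes were recovered in 69% of simulated cases by edgeR, so smaller changes can be missed. The simulation changed 200 genes at once, none of them among the genes of lowest level, let genes vary independently and gave 176 calls. The real comparisons had fewer calls, which makes the adjusted threshold stricter, so the share recovered there can be lower than 69%.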

Other observations

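Of the tests in this part, those with the no-feature share as covariate, the comparisons of the indirect with the direct pathway genes, the place of Gas5 among the host genes, the test of NM_001388492 and the choice of the oligodendrocyte list with its test for either direction came after the result was seen. The other tests were set before their results were seen.

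The mature oligodendrocyte list (25 members tested) was not called by camera for genotype (adjusted p = 0.336), for AON12.1 against scrambled (adjusted p = 0.0671), for AON12.1 against aCSF (adjusted p = 0.101) or for scrambled against aCSF (adjusted p = 0.924). For genotype, Enpp6, a marker of newly formed oligodendrocytes, rose by 1.08 ± 0.19 over all genes (adjusted p = 0.00632). Adjusted over the list alone, 1 member was higher and 6 were lower, among them Qdpr (-0.33). By limma's fry, the test for change in either direction gave adjusted p = 0.00224 over 37 lists, and that for one direction adjusted p = 0.660. Also passing fry for either direction were the astrocyte (adjusted p = 0.00224), glucocorticoid response and proteasome (adjusted p = 0.00355 each) and oxidative phosphorylation lists (adjusted p = 0.0125). With AON12.1 against scrambled, 3 members rose over all genes, Qdpr, Gsn and Trf, and 5 were higher and 2 lower adjusted over the list alone (adjusted p = 0.00333 for either direction, adjusted p = 0.771 for one). The myelin gene Mbp (-0.11) was not called in that comparison. With AON12.1 against aCSF, Apod and Gsn rose over all genes, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00753 and adjusted p = 0.511). Other lists passed fry for either direction there too, among them reactive astrocyte genes (adjusted p = 0.0103). With the scrambled oligonucleotide against aCSF, 0 members were called over all genes and 2 were lower adjusted over the list alone, among them Qdpr at -0.33 (adjusted p = 0.249 for either direction). The mean of the AON12.1 group for Qdpr, Gsn, Apod and Mbp includes replicate 2, which stood above the other 7 libraries in each.

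1110038B12Rik and C4b, both on chromosome 17, were higher with AON12.1 than with the scrambled oligonucleotide, and the first, at 2.39, had a larger log2 fold change than the other named genes called in that comparison. A change of the whole region is argued against by the other 31 tested genes within 500 kb of the pair, whose median log2 fold change was -0.0800 (95% bootstrap interval -0.137 to 0.0108) with 0 called by edgeR. With the no-feature share as covariate C4b stood at 1.17 (adjusted p = 4.78e-06). That share differed by 1.71 points between these groups, so its use as covariate could change little. Among mice numbered from 19, 1110038B12Rik stood at 2.32 ± 0.17 (adjusted p = 3.56e-10). Each group held 2 libraries numbered from 18 and 6 from 19, so the number series was balanced and this test could not decide on it. A general rise of small nucleolar RNA host genes by about as much is argued against by 16 tested others, with a median of 0.0211 (interval -0.0660 to 0.155, SD 0.250), though 1 of them, Gas5, rose by 0.74. An action of the AON12.1 sequence on these transcripts may be an explanation but was not tested, and counts shared with the copy C4a stay open for C4b.

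Spata5 and Anxa5, higher in YAC128 than in WT mice, lie on the same chromosome, 3, where a segment linked to the transgene or to strain background could raise several genes. Spata5 and Anxa5 were left out of the genes counted in this test. Of 34 other tested genes within 5 Mb of Spata5, 6 had an unadjusted p under 0.05 between all YAC128 and WT mice, or 17.6%, against a median of 13.2% in 10000 segments centred on random genes. This share lay at percentile 81.9, so a segment effect and separate changes cannot be told apart with so few genes. The no-feature share alone is argued against for Spata5, which stood at 1.55 with it as covariate (adjusted p = 0.00515). The fold of Anxa5 was 0.54 with and without the covariate, and its call ended (adjusted p = 0.105) with an SE of 0.12 in place of 0.11.

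Penk and Adora2a were lower in YAC128 than in WT mice given aCSF, and a candidate explanation is a smaller yield of striatal projection neurons of every kind. This stays open, since the mean log2 CPM of the indirect minus the direct pathway list differed by -0.25 in YAC128 mice (exact permutation test over 12870 splits, two-sided, p = 0.0104), but by -0.109 with Penk and Adora2a themselves left out (-1.06 ± 0.194 against -0.955 ± 0.181, SD, n = 8 each, exact p = 0.261), and 42 of 45 projection neuron genes had lower values. The no-feature share stays open, since Penk stood at -0.66 ± 0.17 with it as covariate against -0.76 ± 0.16 without, and its call ended (adjusted p = 0.296). The fold moved by less than its SE while the SE grew and the transgenic group's share was higher by 6.12 points. A change within indirect-pathway neurons in this model also remains open as a hypothesis.

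NM_001388492 was above the highest WT library (6.90 CPM) in 24 of 24 YAC128 libraries, the lowest of which had 91.4 CPM. This is consistent with a transcript of the transgene, and the identity of the feature was not established from its sequence.

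For each comparison, 100 of the 6435 splits of its 16 libraries into sets of 8 were drawn, the real one included. For the count of called genes at most 3 of the 100 splits, the real one included, gave as many in any comparison. For genotype, AON12.1 against scrambled and AON12.1 against WT, other splits gave more genes than the real one. No adjustment was made over comparisons, so chance is made less likely but not excluded. As many genes came from 3 splits for genotype (8 real, highest other 15), 2 for AON12.1 against scrambled (15, highest other 65), 1 for AON12.1 against aCSF (33, highest other 17), 1 for scrambled against aCSF (9, highest other 7), 3 for AON12.1 against WT (60, highest other 115) and 1 for scrambled against WT (18, highest other 1). The splits with 65 and 115 genes point to a structure of the samples. Their sets differed in the no-feature share by -6.18 and -7.54 points, and that with 17 by -7.20 points, and whether the counts of such splits follow this share was not tested. For lists, chance cannot be excluded for genotype (8 splits, 13 real, highest other 15) or AON12.1 against scrambled (58 splits, 6 real, highest other 15). It is less likely but not excluded for AON12.1 against aCSF (2 splits, 17 real, highest other 17) and scrambled against aCSF (2 splits, 14 real, highest other 14), where another split called as many lists. For the movement of genotype genes chance cannot be excluded in any of the 3 comparisons, with 53 splits for AON12.1 against scrambled (0.05 real, highest other -0.16), 40 for AON12.1 against aCSF (-0.07 real, highest other -0.47) and 13 for scrambled against aCSF (-0.10 real, highest other -0.19).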
